A study of Mus musculus with 24 samples.

How the data were processed

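Sciatic nerve RNA was hybridised to 24 Affymetrix arrays, 2 biological replicates for each of 12 groups (4 genotypes at 3 ages). The values deposited by the authors are log2 expression per probe set, 22690 probe sets per array; the unit was read from the values, and the normalization and software behind them are not given in the sources used here. The values were not log transformed again, and no pseudocount or handling of zeros applied. Depth does not apply to arrays, whose number limits the precision of each value.

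Of the probe sets, 64 are controls, 20380 list 1 gene symbol, 691 several and 1555 none; those with several or none were left out because their signal cannot be assigned to 1 gene. Gene IDs of 20351 probe sets matched the gene table of mouse assembly GRCm38.p6, used for names and for the order of genes only. For the 4956 genes with more than 1 probe set the one with the highest mean over the 24 arrays was used, which leaves 12393 genes. Some genes are not reported here.

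Groups, comparisons, tests, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. Group means of all 24 arrays were fitted with limma 3.58.1 (lmFit and eBayes, statmod 1.5.0, R 4.3.3), so that 12 residual degrees of freedom estimate 1 spread per gene. Each comparison was a contrast of those means, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 24 comparisons are S63del against WT, Chop null against WT and S63del/Chop null against S63del at each age and averaged over ages, their interaction at each age, the difference of the S63del effect between ages, and WT between ages. Of these 5 were added after the data were seen: S63del/Chop null against Chop null at each age, and P5 against 4 months in WT and in the S63del effect.

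For the text, genes were named by a rule: in genotype comparisons the 10 largest rises and 10 largest falls among genes past the threshold whose replicates do not overlap, and 6 each way in other comparisons. It adds up to 4 members of each list with the smallest p, and a fixed set of stress and Schwann cell genes. The text prints part of them. The 26 lists hold 601 genes, 540 of them measured: ER chaperones and folding, ER-associated degradation and translocation, ATF4 amino acid and stress targets, aminoacyl-tRNA synthetases, CHOP-linked targets, myelin, cholesterol synthesis, fatty acid and sphingolipid synthesis, immature and repair Schwann cell, cell cycle, macrophage, antigen presentation and interferon, lymphocytes and mast cells, cytokines and chemokines, skeletal muscle, adipocyte, fibroblast and perineurium, endothelium and pericyte, erythroid, axonal and neuronal, immediate early genes, NRF2 oxidative stress, apoptosis and p53, cytosolic ribosomal proteins, mitochondrial respiration, and sex-linked genes. They were tested with camera (preset correlation of 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry, which does not compare a list with other genes. Some genes stand in 2 lists.

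The score of the mutant effect took, for each array, genes called in S63del against WT at the other 2 ages, so that their changes come from other arrays than those scored, though all arrays share 1 estimate of the spread behind the calls. S63del and S63del/Chop null were compared by an exact permutation test within age (two-sided). For comparisons averaged over ages, 100 of 108 splits within age were drawn with a fixed seed.

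The fit was tested on simulated data with 200 changed genes among 12393, in 3 rounds, for S63del against WT at P5, P28 and 4 months. With equal spread in all groups 2.89%, 4.32% and 5.11% of calls were false, with the spread of each group 0%, 5.85% and 4.0%, and with the spread of each age 2.16%, 45.8% and 11.3%. The version with the spread of each age was written first, was replaced by the other versions when it made many false calls at P28, and was then restored; all are given. Of the calls of Chop null against WT at P28 51.1% were false with the spread of each age and 74.8% with the spread of each group. The spread is largest in P28 Chop null (residual SD 0.278), against 0.146 in WT and 0.136 in S63del at P28 and 0.159 in WT at 4 months.

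Alternatives planned were another quantile normalization, the mean of all probe sets of a gene, a filter on probe sets under the 40th percentile, and the 8 arrays of an age alone (4 residual degrees of freedom). Also planned were array weights, an intensity trend with robust estimation, a replicate block within age, and each array of the groups compared left out in turn. For the score they included the genes called with dim genes left out or at both other ages. Added after the data were seen were fits without Chop null P28 replicate 2 and WT 4-month replicate 1 (for S63del against WT at 4 months also without the former alone or with WT replicate 2), without all P28 arrays, and with the skeletal muscle mean or the Gapdh 3' minus 5' difference as a covariate, and the score with genes called at P5 only. Replicate numbers were checked for pairing: of 18 correlations between the deviations of replicates with the same number 5 exceeded 0.1, so they were not treated as pairs.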

Results

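Gene expression was measured with Affymetrix arrays in whole sciatic nerve of 4 genotypes of mice at 3 ages, with 2 arrays per group labelled as biological replicates and 24 arrays in all. S63del mice carry a mutant myelin protein that causes a demyelinating neuropathy of the Charcot-Marie-Tooth 1B type. Chop null mice lack Ddit3, which encodes CHOP, a transcription factor induced when misfolded protein burdens the endoplasmic reticulum (ER). The other genotypes are wild type (WT) and S63del/Chop null. The ages are postnatal day 5 (P5), when myelination begins, P28, near its peak, and 4 months. Values are log2 expression, with array medians between 6.84 and 7.03; the number of arrays limits the precision of each mean. Changes below are log2 differences ± SE from limma, 2 arrays against 2 unless stated, and a gene counts as changed at an adjusted p under 0.05 among 12393 genes. Chance alone gives an unadjusted p under 0.05 in a share of 0.05 of these genes on average. Counts below that share are no sign of further changes.

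Ddit3 was read in every array as a check of the labels. At P5 its log2 value was 7.66 and 7.62 in WT, 6.85 and 6.60 in Chop null, 9.59 and 9.52 in S63del, and 6.93 and 6.82 in S63del/Chop null. At P28 the values were 8.20 and 8.16 in WT, 6.84 and 7.37 in Chop null, 9.13 and 9.05 in S63del, and 6.78 and 6.77 in S63del/Chop null. At 4 months they were 9.09 and 8.29 in WT, 6.75 and 6.80 in Chop null, 9.21 and 9.002 in S63del, and 6.70 and 6.76 in S63del/Chop null. All 12 arrays of the Chop null genotypes lay below all 12 others.

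**Figure D1:**
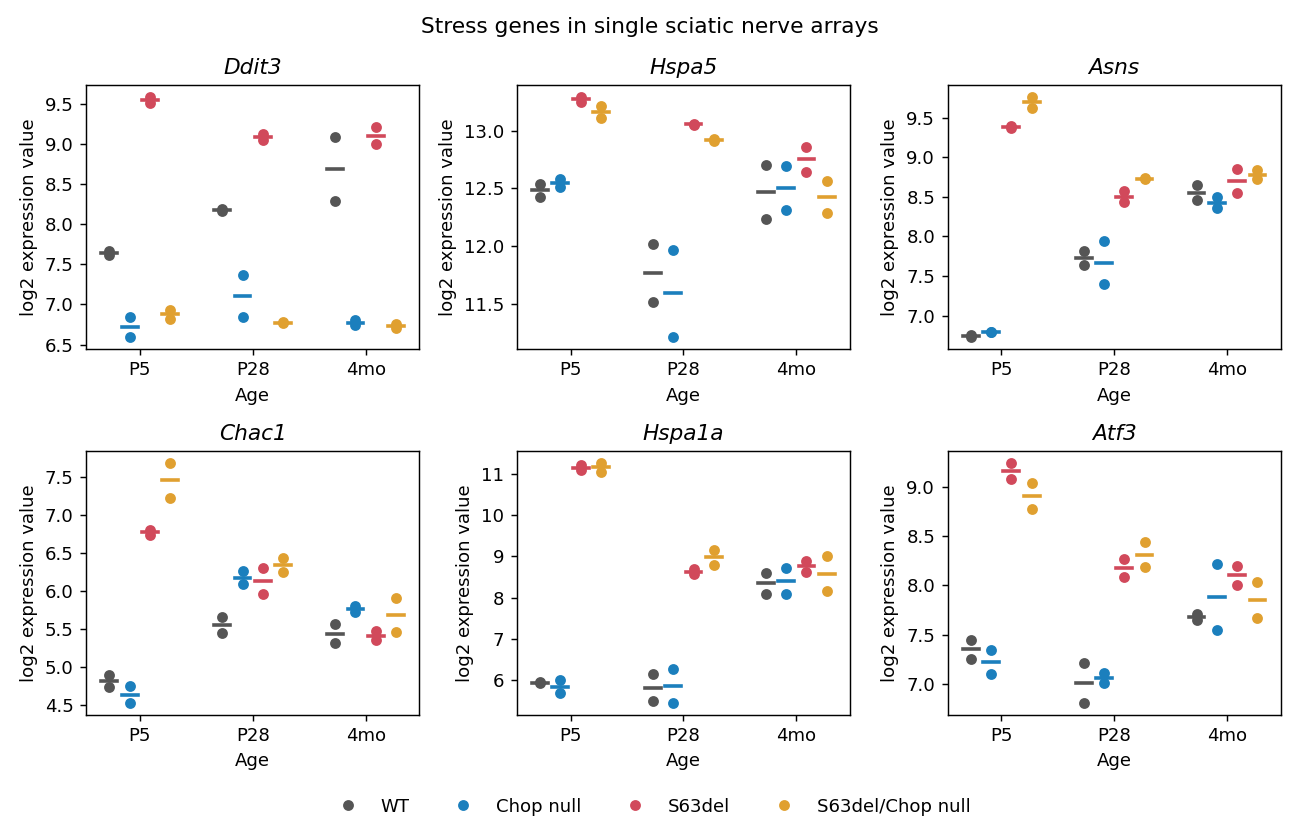
Log2 expression (y axis) of Ddit3, Hspa5, Asns, Chac1, Hspa1a and Atf3 by age (x axis) in the 4 genotypes; each point is an array and each bar a group mean of 2 arrays. Ddit3 lies at 6.60 to 7.37 in the Chop null genotypes and at 7.62 to 9.59 in the others.

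The comparison of S63del with WT at P5 asks for the earliest effects of the mutant protein, before demyelination can add its own. The largest rises were those of Hspa1a by 5.21 ± 0.30 (37.1-fold), Hspa1b by 3.55 ± 0.29 and Hspb1 by 3.48 ± 0.16, which encode heat shock proteins. Asns, which makes asparagine and is a target of the stress factor ATF4, rose by 2.64 ± 0.15, Ddit3 itself by 1.92 ± 0.19, and the ER genes Derl3 and Sdf2l1 by 2.41 ± 0.24 and 2.31 ± 0.20. Genes of sterol and lipid synthesis fell, among them Lss (-2.02 ± 0.28), Tm7sf2 (-2.01 ± 0.20) and Acss2 (-1.76 ± 0.34). In all, 298 genes changed, 142 higher and 156 lower, 95 of them by more than 2-fold, and 1355 genes had an unadjusted p under 0.05.

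Other large rises at P5 were those of Fbxo2 (3.34 ± 0.18), which recognises glycoproteins for degradation, the chemokine Cxcl10 (3.03 ± 0.61), Uchl1 (2.70 ± 0.30) and Lgals3 (2.66 ± 0.27). The largest falls outside lipid synthesis were those of Chst2 (-2.08 ± 0.17), Slc6a15 (-1.98 ± 0.26), the glycolytic enzyme Aldoc (-1.95 ± 0.39), Chdh (-1.90 ± 0.15), the axon guidance gene Sema5a (-1.83 ± 0.17), Serpinb6b (-1.79 ± 0.18) and Nsg2 (-1.73 ± 0.23).

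Of 28 measured ER chaperone genes at P5, 7 rose and 0 fell, and 14 rose when adjusted over the list alone. Examples are Creld2 (1.47 ± 0.23), Pdia4 (0.97 ± 0.12) and Hsp90b1 (0.70 ± 0.13). Hspa5, the main ER chaperone, was 0.79 ± 0.21 higher with an adjusted p = 0.069. The list rose as a group (adjusted p = 4.5e-17, and adjusted p = 0.0052 with an estimated correlation). Pdia4 rested on its brightest probe set, and with the mean of all its probe sets it was 0.47 higher (adjusted p = 0.07, the highest of its alternatives from 4.04e-06). Among 27 genes of ER-associated degradation and translocation, Derl3 and Herpud1 (0.81 ± 0.12) rose, 3 when adjusted over the list alone. The list test gave an adjusted p = 1.96e-08, and an adjusted p = 0.071 with an estimated correlation. In the ATF4 list 5 of 37 rose, 8 when adjusted over the list alone with 1 fall, including Chac1 (1.94 ± 0.17), Atf3 (1.81 ± 0.20), Slc7a3 (1.14 ± 0.17) and Trib3 (1.11 ± 0.18). The list passed both ways (adjusted p = 3.16e-09, and adjusted p = 0.000977 with an estimated correlation). No single aminoacyl-tRNA synthetase passed, in limma, over all genes or adjusted over the list alone (0 of 18), yet 18 of 18 lay above 0 and the group test passed. As a group they gave an adjusted p = 9.98e-09, and an adjusted p = 0.00564 with an estimated correlation. Of 14 CHOP-linked genes 5 rose, 9 when adjusted over the list alone, among them Car6, a carbonic anhydrase (2.18 ± 0.27), and Sqstm1 (0.96 ± 0.17). Camera gave the list an adjusted p = 1.06e-11, and an adjusted p = 0.000977 with an estimated correlation. Ppp1r15a (0.08 ± 0.18), Ero1a (0.05 ± 0.10), Atf4 (0.12 ± 0.12) and Xbp1 (-0.14 ± 0.13) did not pass.

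Of 19 genes of cholesterol synthesis at P5, 16 fell, 19 when adjusted over the list alone, with a median of -1.19. Examples are Nsdhl (-1.32 ± 0.17), Dhcr7 (-1.23 ± 0.13) and Hmgcs1 (-1.12 ± 0.12). The group test gave an adjusted p = 1.74e-39, and an adjusted p = 0.00564 with an estimated correlation. Of 24 genes of fatty acid and sphingolipid synthesis, 10 fell and 1 rose, 16 and 1 when adjusted over the list alone. Elovl6 (-1.503 ± 0.17) and Elovl7 (-1.04 ± 0.14) fell, and Me1 rose by 0.63 ± 0.16. Tested together they gave an adjusted p = 1.09e-16, and an adjusted p = 0.00904 with an estimated correlation. Of 20 myelin genes 7 fell, 9 when adjusted over the list alone, including Fa2h (-1.09 ± 0.14), Ncmap (-1.02 ± 0.13), Ugt8a (-0.86 ± 0.13) and Ndrg1 (-0.67 ± 0.11). Both Fa2h and Ugt8a also stand in the lipid list. The myelin list passed at adjusted p = 4.57e-11, and had an adjusted p = 0.0616 with an estimated correlation. Egr2, the main driver of myelin genes, did not differ detectably (0.00 ± 0.17).

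Immediate early genes rose at P5 (5 of 21, 11 when adjusted over the list alone; adjusted p = 5.43e-13, and adjusted p = 0.00904 with an estimated correlation), with Ccn1 at 1.37 ± 0.16, Ier3 at 1.19 ± 0.14 and Fos at 1.09 ± 0.20. Genes of the oxidative stress factor NRF2 rose too (4 of 18, 6 when adjusted over the list alone with 1 fall; adjusted p = 2.83e-08, and adjusted p = 0.0111 with an estimated correlation), led by Srxn1 at 2.04 ± 0.27. Among 29 genes of immature and repair Schwann cells, Uchl1 and the growth factor Gdnf (1.63 ± 0.24) rose, 3 when adjusted over the list alone. For the whole list camera gave an adjusted p = 0.000301, and an adjusted p = 0.0931 with an estimated correlation. Jun (0.53 ± 0.20), Sox2 (0.58 ± 0.38), Pou3f1 (0.32 ± 0.35) and Id2 (0.48 ± 0.24) did not pass. The cell cycle list had 0 of 29 genes past the threshold in limma, also adjusted over the list alone, with a median of 0.41. The test of all members gave an adjusted p = 5.04e-10, and an adjusted p = 0.0681 with an estimated correlation. Chemokines rose in 4 of 20 cases, 6 when adjusted over the list alone, among them Ccl8 (2.22 ± 0.37), Cxcl14 (2.10 ± 0.30) and Ccl2 (1.13 ± 0.28). Taken as a list they gave an adjusted p = 0.000301, and an adjusted p = 0.0625 with an estimated correlation.

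The remaining lists, mostly of other cells, were tested at P5 in the same way. Fibroblast and perineurial genes fell (2 of 21, 5 when adjusted over the list alone; adjusted p = 9.06e-08, and adjusted p = 0.0111 with an estimated correlation), with Itgbl1 at -0.88 ± 0.18 and Ogn at -0.78 ± 0.13. Vwf (-0.76 ± 0.17) fell among 20 endothelial and pericyte genes, 6 when adjusted over the list alone, but was -0.48 without S63del replicate 2 (adjusted p = 0.439, the highest of its alternatives from 0.00396). The list test gave an adjusted p = 2.92e-06, and an adjusted p = 0.0514 with an estimated correlation. Of 26 macrophage genes Lgals3 and Gpnmb (1.05 ± 0.21) rose, also 2 when adjusted over the list alone, but the list median was 0.02. As a group they gave an adjusted p = 0.0333, and an adjusted p = 0.407 with an estimated correlation. Tubb3 (2.25 ± 0.21), Eno2 (0.77 ± 0.18) and Uchl1 rose among 15 axonal and neuronal genes, 3 when adjusted over the list alone (adjusted p = 0.0949 for the list). H2-DMa (-1.62 ± 0.19) fell as the only one of 17 antigen presentation genes to pass, also when adjusted over the list alone (adjusted p = 0.31 for the list). The erythroid list had a median of -0.32 over 8 genes (adjusted p = 0.0352, and adjusted p = 0.293 with an estimated correlation) and the ribosomal protein list a median of 0.08 over 22 genes. Camera gave the ribosomal list an adjusted p = 0.00237, and an adjusted p = 0.288 with an estimated correlation. No gene passed, adjusted over the list alone or over all genes, among the lists of lymphocytes and mast cells (20 genes, median -0.05 and mean 0.02, adjusted p = 0.732) and skeletal muscle (24 genes, median -0.38 and mean -0.18 although the test points up, adjusted p = 0.833). The same holds for adipocytes (14 genes, median -0.22, adjusted p = 0.195), mitochondrial respiration (27 genes, adjusted p = 0.732) and sex-linked genes (4 genes, median 0.50, adjusted p = 0.155). Of 18 apoptosis and p53 genes 0 passed over all genes and 2 rose when adjusted over the list alone (adjusted p = 0.109 for the list).

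The P5 count fell to between 119 and 149 when any of the 4 arrays was left out, in order 131 and 136 without WT replicate 1 or 2 and 149 and 119 without S63del replicate 1 or 2. It was 901 in a fit of the 8 P5 arrays and 1033 with array weights, 572 without Chop null P28 replicate 2 and WT 4-month replicate 1 and 564 without the P28 arrays. With the mean of all probe sets Lss was -1.31 and Aldoc -1.12, both still called, and 16 of the 57 called genes chosen by the naming rule lost the threshold under some alternative.

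**Figure D2:**
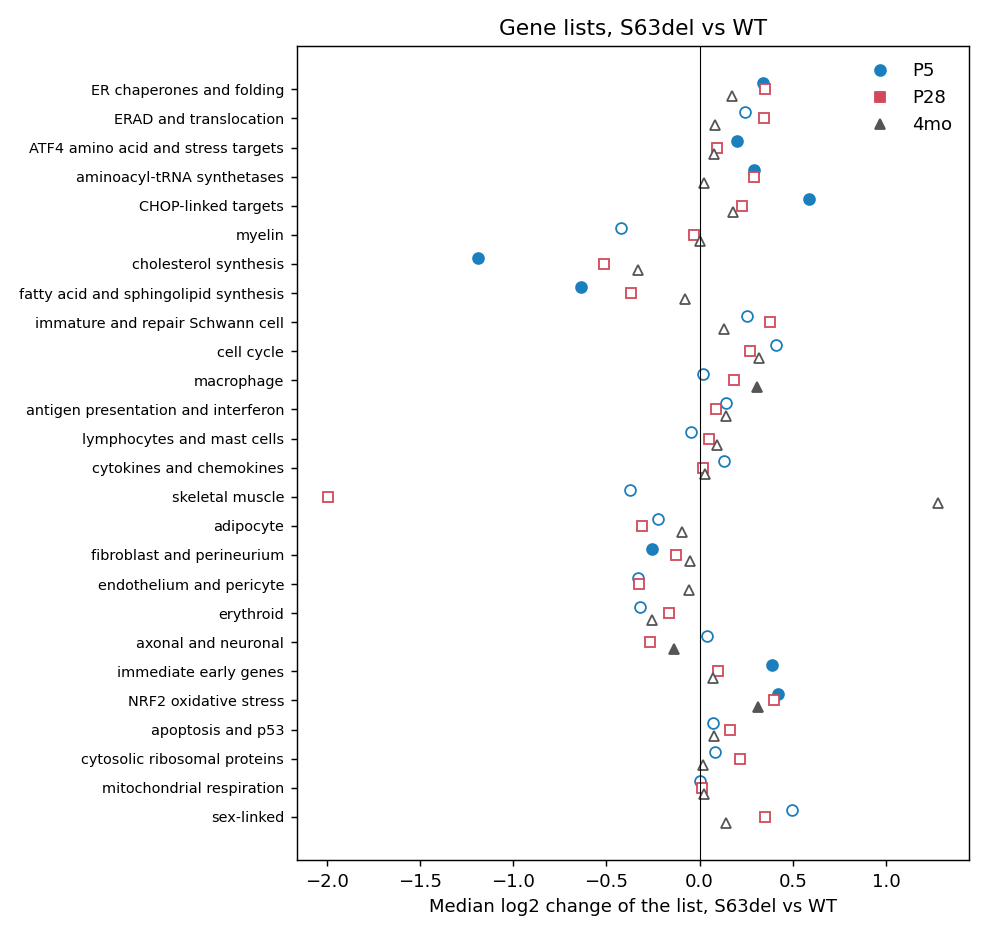
Median log2 change, S63del minus WT (x axis), of each of the 26 gene lists (y axis) at the 3 ages, 1 marker per list and age; filled markers are lists past the threshold with an estimated correlation. The cholesterol synthesis list lies at -1.19 at P5, -0.51 at P28 and -0.33 at 4 months.

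At P28, near the peak of myelination, the same comparison asks what the mutant protein does once myelination runs at full pace. Hspa1a was again among the largest rises (2.81 ± 0.30), with the chemokine Cxcl14 (2.81 ± 0.30), the WNT inhibitor Wif1 (2.66 ± 0.49), Uchl1 (2.20 ± 0.30) and the protease inhibitor Timp1 (2.14 ± 0.32). Sox2 (2.19 ± 0.38) and Pou3f1 (2.10 ± 0.35), transcription factors of Schwann cells that have not yet myelinated, rose with Id2 (1.41 ± 0.24) and Jun (0.80 ± 0.20). Aldoc (-2.50 ± 0.39) and the neuroendocrine chaperone Scg5 (-1.75 ± 0.33) fell. In all 572 genes changed, 373 higher and 199 lower, 107 by more than 2-fold, with 2664 at an unadjusted p under 0.05.

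Further rises at P28 were those of Gcg (3.004 ± 0.70), the acute phase gene Saa1 (2.26 ± 0.30) and Csrp2 (2.13 ± 0.19). Further falls were those of Rpl27a (-2.97 ± 0.25), Hba-a2 (-2.15 ± 0.18), Agbl5 (-2.09 ± 0.17), Cnmd (-1.79 ± 0.35), Kdelr2 (-1.75 ± 0.23), Gatad1 (-1.65 ± 0.18), Pla2g5 (-1.64 ± 0.33) and Elovl4 (-1.61 ± 0.42). With the mean of all probe sets of a gene several changes were over 1.5 times smaller though still called: Rpl27a -1.64, Aldoc -1.61, Agbl5 -1.33, Kdelr2 -0.95 and Gatad1 -0.76, and, among genes named below, Lss -1.04 and Ngfr 0.77. For Rpl27a the group means were 9.18 in WT and 9.42 in Chop null against 6.21 in S63del and 6.36 in S63del/Chop null. The 18S ribosomal RNA control moved the same way at P28: it lay between 9.43 and 10.6 in WT and Chop null and between 5.92 and 6.71 in both S63del genotypes (exact permutation test, two-sided, p = 0.0286, the smallest the design allows, 0.15 after Benjamini-Hochberg adjustment over 21 tests). The same p was reached at P28 by the interquartile range of the log2 values (mean 3.46 in both S63del genotypes against 3.20) and by Xist (mean 11.3 against 10.9), and at P5 by the erythroid mean (7.06 against 7.54). Both P28 margins were narrow. The interquartile range reached 3.381 in WT and Chop null and began at 3.383 in both S63del genotypes. For Xist these values were 11.17 and 11.22. The sex of the mice is not given in the sources used here. Y-linked genes were not lower at P28 where Xist was higher. In WT and Chop null Eif2s3y read 5.76 to 7.08, Kdm5d 5.38 to 6.09 and Uty 4.93 to 5.27. In both S63del genotypes they read 6.44 to 7.12, 5.71 to 6.44 and 5.11 to 5.61.

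ER chaperones rose in 10 of 28 cases at P28, 14 when adjusted over the list alone, among them Sdf2l1 (1.71 ± 0.20), Creld2 (1.54 ± 0.23) and Hspa5 (1.28 ± 0.21). The list passed at adjusted p = 8.19e-10 but had an adjusted p = 0.11 with an estimated correlation. Pdia4 was 0.72 ± 0.12 higher by its brightest probe set and -0.05 with the mean of all its probe sets (adjusted p = 0.857, the highest of its alternatives from 0.00122). Of 27 genes of ER-associated degradation and translocation 7 rose, 11 when adjusted over the list alone, including Derl3 (1.30 ± 0.24), Syvn1 (0.96 ± 0.15) and Sec11c (0.91 ± 0.17). Xbp1, also called there, was 0.63 ± 0.13 higher but 0.24 with the mean of all its probe sets (adjusted p = 0.193, its alternatives running from 0.00289 to 0.272). The group test gave an adjusted p = 1.58e-09, and an adjusted p = 0.208 with an estimated correlation. The ATF4 list did not pass (adjusted p = 0.145), though Atf3 (1.16 ± 0.20), Psph (0.87 ± 0.19) and Asns (0.77 ± 0.15) rose, 5 of 37 when adjusted over the list alone. Among tRNA synthetases Rars (0.55 ± 0.12) and Lars (0.49 ± 0.11) rose, also 2 of 18 when adjusted over the list alone. Tested together they gave an adjusted p = 0.0012, and an adjusted p = 0.208 with an estimated correlation. Dnajc12 (0.58 ± 0.15) rose among 14 CHOP-linked genes, 4 when adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.212 with an estimated correlation). Ddit3 rose by 0.91 ± 0.19 (adjusted p = 0.0133), and its adjusted p ran from 7.34e-05 to 0.119 over the alternatives. It did not pass in the fit of the 8 P28 arrays (adjusted p = 0.118) or without WT replicate 1 (adjusted p = 0.0986), S63del replicate 1 (adjusted p = 0.119) or S63del replicate 2 (adjusted p = 0.0597). Chac1 (0.58 ± 0.17), Ppp1r15a (0.51 ± 0.18) and Trib3 (0.14 ± 0.18) did not pass.

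Immature and repair Schwann cell genes rose in 10 of 29 cases at P28, 11 with 2 falls when adjusted over the list alone, among them Gfap (1.43 ± 0.22) and the neurotrophin receptor Ngfr (1.27 ± 0.20). For the whole list camera gave an adjusted p = 0.000264, and an adjusted p = 0.212 with an estimated correlation. Cell cycle genes rose in 5 of 29, 8 when adjusted over the list alone, such as Cks2 (0.96 ± 0.25), Cdk1 (0.87 ± 0.23) and Rrm2 (0.86 ± 0.21). The test of all members gave an adjusted p = 0.000375, and an adjusted p = 0.292 with an estimated correlation. Macrophage genes rose in 6 of 26, 7 with 1 fall when adjusted over the list alone, such as Lgals3 (1.55 ± 0.27), Ms4a7 (0.97 ± 0.20) and Ctss (0.96 ± 0.23). Taken as a list they gave an adjusted p = 0.00179, and an adjusted p = 0.278 with an estimated correlation. The mast cell tryptases Tpsab1 (1.62 ± 0.31) and Tpsb2 (0.88 ± 0.23) also rose. Their list of 20, with 2 rises also when adjusted over the list alone, did not pass (adjusted p = 0.515). Cholesterol synthesis fell in 4 of 19 genes, 12 when adjusted over the list alone, among them Lss (-1.57 ± 0.28) and Tm7sf2 (-1.19 ± 0.20). The list test gave an adjusted p = 1.96e-09, and an adjusted p = 0.212 with an estimated correlation. Elovl6 (-0.96 ± 0.17), Fads1 (-0.87 ± 0.17), Me1 (-0.73 ± 0.16) and Scd2 (-0.46 ± 0.11) fell among 24 fatty acid and sphingolipid genes, 7 with 1 rise when adjusted over the list alone. As a group they gave an adjusted p = 0.00034, and an adjusted p = 0.214 with an estimated correlation. Only Mal (-0.41 ± 0.10) fell among 20 myelin genes over all genes tested, 2 when adjusted over the list alone, and the list did not pass (adjusted p = 0.391, median -0.03 and mean 0.00).

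Ribosomal protein genes rose at P28 in 2 of 22 cases, 9 when adjusted over the list alone, with Rpl12 at 0.55 ± 0.15 and Rpsa at 0.35 ± 0.09 (adjusted p = 1.49e-05, and adjusted p = 0.212 with an estimated correlation), opposite to the 18S control. Skeletal muscle genes had a median of -2.00 with 0 of 24 past the threshold in limma, over all genes or adjusted over the list alone. Camera gave the list an adjusted p = 0.00016, and an adjusted p = 0.443 with an estimated correlation. The mean of the muscle list ranged from 6.14 to 10.5 over the 24 arrays, and at P28 was 8.22 in both S63del genotypes against 9.61 in the others (exact permutation test, two-sided, p = 0.171). Col14a1 (-0.59 ± 0.10), Mfap5 (-0.55 ± 0.14) and Ogn (-0.47 ± 0.13) fell among 21 fibroblast genes, 5 when adjusted over the list alone. The group test gave an adjusted p = 0.00979, and an adjusted p = 0.214 with an estimated correlation. Endothelial and pericyte genes had a median of -0.32 with 7 falls and 1 rise when adjusted over the list alone and 0 over all genes. Tested together they gave an adjusted p = 7.1e-05, and an adjusted p = 0.208 with an estimated correlation. Srxn1 (1.24 ± 0.27) rose in the NRF2 list, where Me1 fell, and 10 rose and 1 fell when adjusted over the list alone. For the whole list camera gave an adjusted p = 0.00979, and an adjusted p = 0.214 with an estimated correlation. Fos rose by 1.33 ± 0.20 among immediate early genes, 5 when adjusted over the list alone (adjusted p = 0.0233, and adjusted p = 0.352 with an estimated correlation). The neurofilament gene Nefh fell (-0.73 ± 0.19) while Uchl1 rose among 15 axonal and neuronal genes, 2 fell and 1 rose when adjusted over the list alone, and the list did not pass (adjusted p = 0.0957).

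The P28 count, less certain than that at P5, was 59 in a fit of the 8 P28 arrays alone, 274 with the muscle mean as a covariate, and 113, 121 or 189 without WT replicate 1, S63del replicate 1 or S63del replicate 2. It was 663 without WT replicate 2, 683 when quantile normalized again, 729 with dim genes left out, 741 with an intensity trend and robust estimation, and 1761 without Chop null P28 replicate 2 and WT 4-month replicate 1. In simulated data the share of false calls at P28 was 4.32% with equal spread, 5.85% with the spread of each group and 45.8% with the spread of each age (399 of 871), which includes the wide Chop null arrays. Of 69 called genes chosen by the naming rule 54 lost the threshold under some alternative, and with the mean of all probe sets Srxn1 was 0.71 (adjusted p = 0.107, range 0.00783 to 0.132), Tpsb2 0.49 (adjusted p = 0.12, range 0.00376 to 0.33), Rpsa 0.15 (adjusted p = 0.405, range 0.00662 to 0.461) and Scd2 -0.89 (adjusted p = 0.208, range 0.00475 to 0.337).

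At 4 months the comparison asks for later, secondary effects of the disease. No gene passed in limma (0 of 12393, with 577 at an unadjusted p under 0.05 and a smallest adjusted p = 0.168). The largest difference among the genes named was in Myh1, a muscle gene (3.97 ± 0.92, adjusted p = 0.589), followed by the muscle gene Mb (2.36 ± 0.76, adjusted p = 0.759) and Cxcl10 (2.22 ± 0.61, adjusted p = 0.589). Ddit3 was 0.42 ± 0.19 higher, Hspa5 0.28 ± 0.21, Asns 0.15 ± 0.15 and Chac1 -0.03 ± 0.17, none past the threshold. In WT replicates 1 and 2 Ddit3 read 9.09 and 8.29 and Hspa5 12.7 and 12.24. In S63del they read 9.21 and 9.002, and 12.86 and 12.64, so both differences depend on the WT array. NRF2 genes rose together, 7 of 18 when adjusted over the list alone and 0 over all genes (adjusted p = 6.92e-13, and adjusted p = 0.0126 with an estimated correlation), with Nqo1 at 1.68 ± 0.47, Srxn1 at 0.99 ± 0.27 and Hmox1 at 0.63 ± 0.17. Camera also passed macrophage genes upward, 4 of 26 when adjusted over the list alone (adjusted p = 3e-13, and adjusted p = 0.0435 with an estimated correlation), with Lgals3 at 0.93 ± 0.27 and Cybb at 0.71 ± 0.16. It passed axonal and neuronal genes downward, 3 of 15 with 1 rise when adjusted over the list alone (adjusted p = 0.00386, and adjusted p = 0.0435 with an estimated correlation), with Snap25 at -0.82 ± 0.26, Stmn2 at -0.68 ± 0.21 and Nefh at -0.65 ± 0.19. With fry 1 of the 26 lists passed, NRF2 (adjusted p = 0.00801), and macrophage and axonal genes each had an adjusted p = 0.0545. NRF2 genes were also higher in Chop null than in WT, which shares the WT arrays (median 0.21, adjusted p = 5.41e-05, and adjusted p = 0.336 with an estimated correlation). All 19 cholesterol genes lay below 0, 1 of them past the threshold when adjusted over the list alone, with Sqle at -0.64 ± 0.17. The test of all members gave an adjusted p = 6.92e-13, and an adjusted p = 0.138 with an estimated correlation. The muscle list had a median of 1.28 (adjusted p = 1.2e-07, and adjusted p = 0.348 with an estimated correlation). WT replicate 1 at 4 months had a Gapdh 3' minus 5' signal of 2.12, the highest of the 24 arrays, followed by S63del replicates 1 and 2 at 4 months with 1.32 and 1.05, while the other 5 arrays of that age lay between -0.04 and 0.55. Without WT replicate 1 or 2 the count was 2 or 8, without S63del replicate 1 it was 12, and without both WT replicate 1 and Chop null P28 replicate 2 it was 39.

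Averaged over the ages, 6 arrays against 6, 854 genes differed between S63del and WT, 476 higher and 378 lower, with 2627 at an unadjusted p under 0.05. Among called genes whose arrays did not overlap between the genotypes at any age, the largest rises were those of Hspa1a (2.81 ± 0.17), Gcg (2.31 ± 0.40), Cxcl10 (2.27 ± 0.35), Uchl1 (1.96 ± 0.17), Cxcl14 (1.76 ± 0.17), Lgals3 (1.71 ± 0.15), Sdf2l1 (1.53 ± 0.12), Timp1 (1.48 ± 0.19), Wif1 (1.46 ± 0.28) and the pigment gene Tyrp1 (1.43 ± 0.34). The largest falls among them were those of Aldoc (-2.10 ± 0.22), Lss (-1.40 ± 0.16), Tm7sf2 (-1.27 ± 0.12), Scg5 (-1.22 ± 0.19), Pdzph1 (-1.16 ± 0.16), Pla2g5 (-1.10 ± 0.19), Scn3b (-1.09 ± 0.11), Cd24a (-1.09 ± 0.14), Cnmd (-1.05 ± 0.20) and Pcsk6 (-1.02 ± 0.23). Ddit3 rose by 1.08 ± 0.11, Asns by 1.19 ± 0.09, Atf3 by 1.13 ± 0.11, Sox2 by 1.13 ± 0.22, Pou3f1 by 1.11 ± 0.20 and Hspa5 by 0.78 ± 0.12. In 6 lists the call held with an estimated correlation. They are ER chaperones (14 of 28 rose, 17 when adjusted over the list alone, adjusted p = 0.00951), CHOP-linked genes (6 of 14, 9 when adjusted over the list alone, adjusted p = 0.00951) and ATF4 genes (8 of 37 rose and 2 fell, 13 and 2 when adjusted over the list alone, adjusted p = 0.0135). The others are NRF2 genes (10 of 18, 13 with 1 fall when adjusted over the list alone, adjusted p = 0.0174), tRNA synthetases (3 of 18, 5 when adjusted over the list alone, adjusted p = 0.021) and cholesterol synthesis (17 of 19 fell, 19 when adjusted over the list alone, adjusted p = 0.021). Of 84 called genes chosen by the naming rule 33 lost the threshold under some alternative. Without the P28 arrays Sox2 was 0.60 (adjusted p = 0.0589, the highest of its alternatives from 0.000286), Pou3f1 0.62 (adjusted p = 0.201, the highest from 0.00201), Wif1 0.87 (adjusted p = 0.275, the highest from 0.00323) and Cnmd -0.68 (adjusted p = 0.206, the highest from 0.00252). Without S63del P5 replicate 2 the count was 499, without S63del 4-month replicate 2 it was 501, and without all P28 arrays it was 455. It was 1230 with array weights and 1900 without Chop null P28 replicate 2 and WT 4-month replicate 1, and with the mean of all probe sets Aldoc was -1.29 and Lss -0.88, both still called. Leaving out WT P5 replicate 2, S63del P28 replicate 1, S63del 4-month replicate 1 or WT P5 replicate 1 gave 523, 511, 539 and 554, and WT P28 replicate 1 gave 563.

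The effect of S63del was then compared between ages, by the difference of the S63del minus WT changes. From P5 to P28 it differed in 59 genes (30 higher, 29 lower at P28, with 1006 at an unadjusted p under 0.05). The effect on Asns fell by 1.87 on the log2 scale and that on Chac1 by 1.36, and that on Gfap rose by 1.72 ± 0.31. Both ATF4 genes (adjusted p = 0.0154 with an estimated correlation) and axonal genes (adjusted p = 0.0154 with an estimated correlation) had lower effects at P28, with list medians of -0.17 and -0.34. From P28 to 4 months it differed in 21 genes (14 higher, 7 lower; 1064 unadjusted). From P5 to 4 months, a comparison added after the data were seen, it differed in 35 genes (18 higher, 17 lower, with 608 unadjusted). The effect fell by 1.501 on the log2 scale for Ddit3, by 1.97 for Chac1 and by 1.73 for Sdf2l1, and that on Dhcr7 rose by 1.00 ± 0.19. For Ddit3 the WT values rose (7.66 and 7.62 at P5, 9.09 and 8.29 at 4 months) while S63del fell less (9.59 and 9.52, then 9.21 and 9.002). For Chac1 the S63del values fell (6.80 and 6.74, then 5.35 and 5.475) while WT rose less (4.90 and 4.745, then 5.57 and 5.31). In that comparison the CHOP-linked list had a median of -0.42 (adjusted p = 0.00362 with an estimated correlation) and the cholesterol list a median of 0.80 (adjusted p = 0.0221 with an estimated correlation). Of the 142 genes higher in S63del at P5, 133 lay above 0 at P28 (median 0.52) and 122 at 4 months (median 0.20). Of the 156 lower ones 134 lay below 0 at P28 (median -0.30) and 119 at 4 months (median -0.16). Genes called at both P5 and P28 numbered 59 higher, 37 lower and 3 in opposite directions, against 4.27 and 2.5 shared by chance. The P5 to P28 count was 17 without S63del P28 replicate 1 and between 23 and 36 without each of 6 other arrays (45 without WT P28 replicate 2). The P5 to 4 months count was 13 without WT P5 replicate 1 and 60 without WT 4-month replicate 2. It was between 15 and 20 without WT 4-month replicate 1, S63del 4-month replicate 2, S63del P5 replicate 2 or WT P5 replicate 2. The P28 to 4 months count was 5, 5, 6, 7 and 13 without S63del P28 replicate 1, S63del 4-month replicate 2, WT P28 replicate 1, S63del P28 replicate 2 and S63del 4-month replicate 1. Without both Chop null P28 replicate 2 and WT 4-month replicate 1 the counts were 213 (P5 to P28), 121 (P28 to 4 months) and 59 (P5 to 4 months).

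Chop null against WT asks what loss of Chop does without the mutant protein. Ddit3 was the only gene called, at -1.92 ± 0.19 at 4 months (adjusted p = 0.000272) and -1.30 ± 0.11 averaged over ages (adjusted p = 2.49e-05). At P5 it was -0.91 ± 0.19 (adjusted p = 1) and at P28 -1.07 ± 0.19 (adjusted p = 0.119), and limma called 0 genes at both ages. There were 114 and 1244 at an unadjusted p under 0.05 at P5 and P28, and 733 and 631 at 4 months and averaged over ages. Averaged over ages Atf5, a stress factor downstream of CHOP, was -0.40 ± 0.10 (adjusted p = 0.888) and Pdia4 0.23 ± 0.07 (adjusted p = 0.888). Of the 26 lists, skeletal muscle (median 0.42, adjusted p = 2.05e-05, and adjusted p = 0.999 with an estimated correlation) and endothelium and pericytes (median -0.17, 4 of 20 lower when adjusted over the list alone, adjusted p = 4.41e-06, and adjusted p = 0.335 with an estimated correlation) passed. The P28 count was 3484 without Chop null replicate 1 and 14 without Chop null replicate 2, the averaged count 824 and 2 without the same arrays and 19, 4 and 2 without WT 4-month replicate 2, Chop null 4-month replicate 2 and Chop null P5 replicate 1. The 4-month count was 361 without WT replicate 2 and 6 without Chop null replicate 2. The fit of the 8 arrays of 4 months called 0 genes, with an adjusted p = 0.678 for Ddit3, the highest of its alternatives from 3.88e-06.

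S63del/Chop null against S63del is the rescue comparison: it asks which effects of the mutant protein need Chop. Ddit3 fell, with changes of -2.68 ± 0.19 at P5 (adjusted p = 1.79e-06), -2.32 ± 0.19 at P28 (adjusted p = 1.63e-05), -2.38 ± 0.19 at 4 months (adjusted p = 1.11e-05) and -2.46 ± 0.11 averaged over ages (adjusted p = 1.14e-09). The only other gene called was Car6 at P5 (-2.24 ± 0.27, adjusted p = 0.00167), against its rise of 2.18 ± 0.27 in S63del over WT. Its probe set is dim, with a mean of 3.88 over the 24 arrays and 5.75 in S63del at P5, under the 6.19 of the filter on dim probe sets, so that filter leaves Ddit3 alone at P5. Counts at an unadjusted p under 0.05 were 110, 466, 274 and 240. Averaged over ages Atf5 was -0.58 ± 0.10 (adjusted p = 0.108), Trib3 -0.29 ± 0.11, Ero1a -0.16 ± 0.06, Ppp1r15a -0.01 ± 0.10, Hspa5 -0.19 ± 0.12, Asns 0.21 ± 0.09 and Chac1 0.39 ± 0.10, each with an adjusted p = 1 after Atf5. The CHOP-linked list fell at P5 (1 of 14, Car6, fell; 3 fell and 1 rose when adjusted over the list alone; adjusted p = 0.000461, and adjusted p = 0.143 with an estimated correlation). At 4 months all 19 cholesterol genes lay above 0 (median 0.28, adjusted p = 3.8e-12, and adjusted p = 0.317 with an estimated correlation) and ER chaperones had a median of -0.10. Taken as a list the chaperones gave an adjusted p = 0.00153, and an adjusted p = 0.447 with an estimated correlation. The Gapdh 3' minus 5' signal parted the same arrays (1.32 and 1.05 in S63del, 0.35 and 0.55 in S63del/Chop null), so these list changes go with RNA quality as well as with genotype. Sex-linked genes differed there too, with Kdm5d at -1.81, Eif2s3y at -1.43 and Xist at 0.92, 3 of 4 lower when adjusted over the list alone (adjusted p = 0.000109, and adjusted p = 0.0971 with an estimated correlation). At P28 all 20 endothelial and pericyte genes lay above 0 (adjusted p = 6.01e-09, and adjusted p = 0.106 with an estimated correlation). Car6 did not pass without S63del replicate 1 (adjusted p = 0.0887, the highest of its alternatives from 2.59e-08). The 4-month count was 17 without S63del/Chop null replicate 2, 5 without S63del replicate 1 and 0 in the fit of the 8 arrays of that age, where Ddit3 had an adjusted p = 0.156 (other alternatives from 3.12e-09). The averaged count was 2 without S63del 4-month replicate 1 or S63del/Chop null 4-month replicate 2, and the P5 count 4 without S63del/Chop null replicate 1 and 1 without S63del replicate 1.

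Whether the effect of S63del differed with and without Chop was tested directly as an interaction. Limma called 0 genes at P5, P28 and 4 months, with 107, 972 and 322 at an unadjusted p under 0.05 and smallest adjusted p = 0.0846, 0.171 and 1. At P5 the largest named differences were Car6 at -2.17 ± 0.39 (adjusted p = 0.196) and Ddit3 at -1.76 ± 0.28 (adjusted p = 0.0846). The only list to pass with an estimated correlation was NRF2 at 4 months (median -0.27, 4 of 18 lower when adjusted over the list alone, adjusted p = 8.02e-10, and adjusted p = 0.0315 with an estimated correlation), though not with fry (adjusted p = 0.11). Without Chop null P28 replicate 1 the P28 count was 2239, and without S63del/Chop null 4-month replicate 2, WT 4-month replicate 2 or Chop null 4-month replicate 2 that at 4 months was 17, 6 or 5.

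The effect of S63del without Chop, S63del/Chop null against Chop null, was added after the data were seen to stand beside that with Chop. It changed 221 genes at P5 (112 higher, 109 lower), again led by Hspa1a (5.32 ± 0.30), Hspb1 (3.76 ± 0.16) and Hspa1b (3.65 ± 0.29), with Chac1 at 2.81 ± 0.17, Asns at 2.90 ± 0.15 and Lss at -1.92 ± 0.28. With S63del against WT it shared 92 higher and 95 lower genes, where chance gives 1.28 and 1.37; 297 of the 298 genes had the same sign. The P5 count was between 78 and 103 when any 1 of its 4 arrays was left out, 586 in the fit of the 8 P5 arrays and 935 with array weights. Pearson's r across the 12393 genes was 0.779 and Spearman's rho 0.591; genes are not independent replicates. At P28 it called 2209 genes (1211 higher, 998 lower), of which 238 higher and 131 lower were shared with S63del against WT (chance 36.4 and 16), and r across genes was 0.69 (rho 0.659). Chance is a weak yardstick at P28, since the 18S control parts both S63del genotypes from WT and Chop null there. The interquartile range and Xist part them too, by narrow margins, so both comparisons carry the same array differences. That count was 5988 without Chop null replicate 1, 538 without S63del/Chop null replicate 2, 553 without Chop null replicate 2, 946 without S63del/Chop null replicate 1, 84 in the fit of the 8 P28 arrays and 14 with array weights. At 4 months 0 genes were called in limma (181 at an unadjusted p under 0.05) and r across genes was 0.0778.

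**Figure D3:**
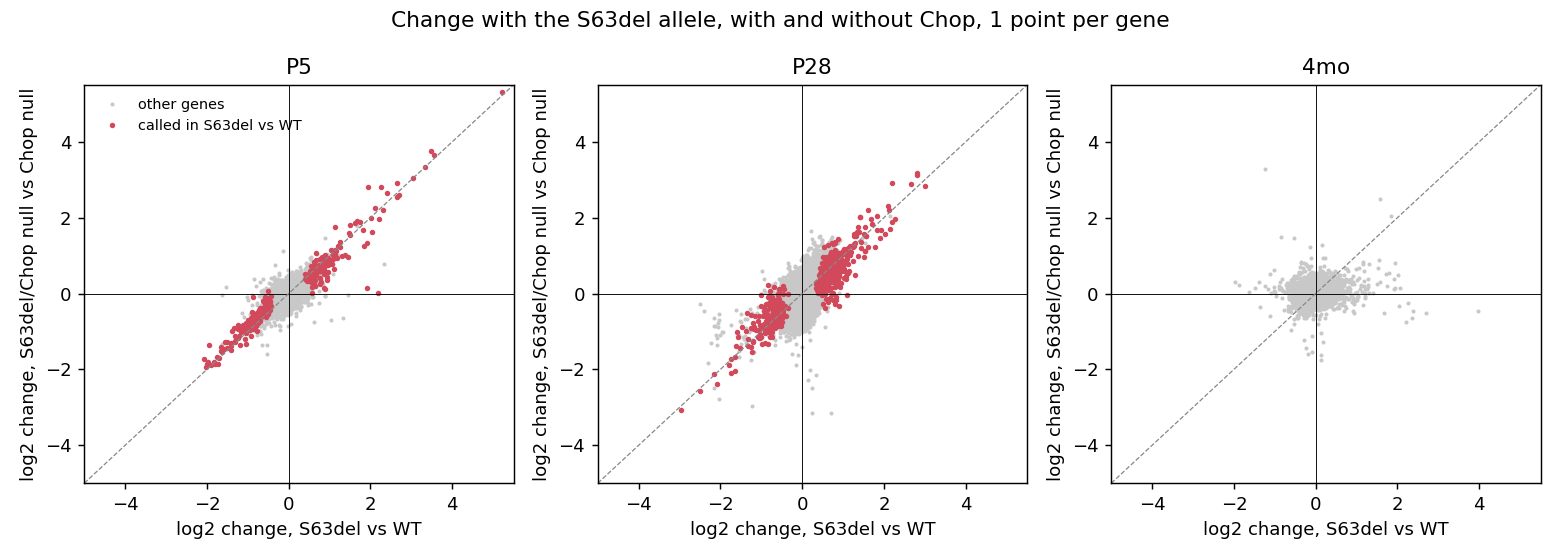
Log2 change S63del minus WT (x axis) against S63del/Chop null minus Chop null (y axis) at P5, P28 and 4 months, 1 point per gene; red points are genes called in S63del against WT and the dashed line marks equal change. Across genes r is 0.779 at P5, 0.69 at P28 and 0.0778 at 4 months.

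A score summed up the mutant effect per array as the mean change, signed by direction, of the genes called in S63del against WT at the other ages. It was 0.333 in S63del and 0.309 in S63del/Chop null at P5 (572 genes), 0.469 and 0.448 at P28 (298 genes), and 0.176 and 0.0593 at 4 months (768 genes), each mean over n = 2 arrays. In Chop null it was 0.0125, 0.00898 and 0.0667. The mean difference between S63del and S63del/Chop null was 0.0543 (exact permutation test within age, two-sided, p = 0.0463, smallest possible p = 0.00926). Most of it came from 4 months, where S63del had an SD of 0.00184 and S63del/Chop null an SD of 0.174 between its 2 arrays, and without S63del/Chop null 4-month replicate 1 the difference was 0.0134 (exact permutation test, p = 0.0926). It passed the threshold in 3 of 12 cases with 1 array left out, and exact permutation p over the alternatives able to pass ran from 0.00926 to 0.361.

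**Figure D4:**
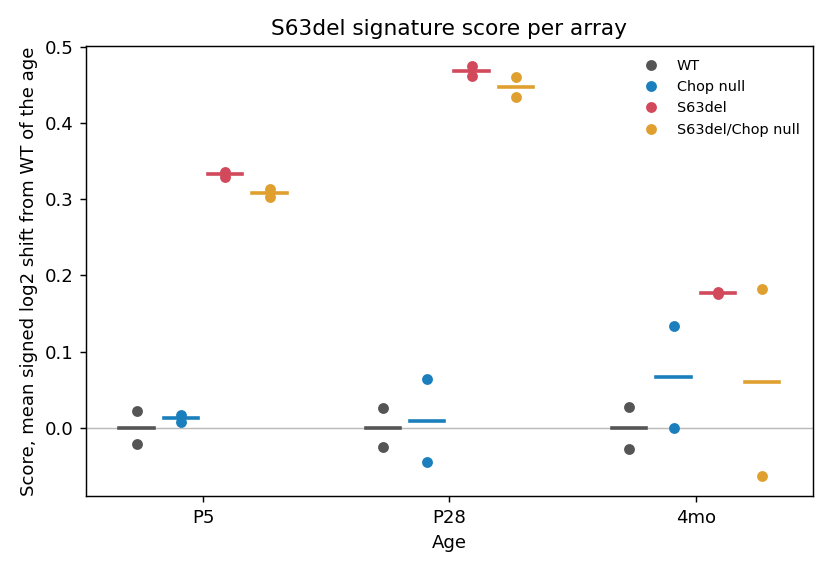
Score of the mutant effect (y axis, mean signed log2 difference from WT of the same age) per array, by age and genotype (x axis); each point is an array. S63del and S63del/Chop null lie at means of 0.333 and 0.309 at P5, 0.469 and 0.448 at P28, and 0.176 and 0.0593 at 4 months.

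Development in WT nerve gives the background. From P5 to P28, 7378 genes changed (3877 higher, 3501 lower; 7954 at an unadjusted p under 0.05). Among the rises were Cyp2e1 (7.55 ± 0.14), Thrsp (5.18 ± 0.58), Inmt (4.92 ± 0.24), Aldh1a1 (4.47 ± 0.23), Gpm6a (4.24 ± 0.19) and Hp (4.05 ± 0.39). Among the falls were Agtr2 (-5.61 ± 0.26), Nrk (-4.44 ± 0.16), Rrm2 (-4.21 ± 0.21), Bex1 (-4.03 ± 0.46), Kcnj10 (-3.98 ± 0.22) and the proliferation marker Mki67 (-3.98 ± 0.29). Sox2 (-3.49 ± 0.38), Pou3f1 (-2.94 ± 0.35) and Id2 (-2.91 ± 0.24) fell as well. Cell cycle genes fell in 28 of 29 cases (median -2.36, adjusted p = 1.51e-17, and adjusted p = 0.0874 with an estimated correlation). From P28 to 4 months 7062 genes changed (3904 higher, 3158 lower; 7727 unadjusted). The largest rises were those of Ripk4 (3.17 ± 0.18), Pkp2 (2.98 ± 0.24), Cyp2f2 (2.96 ± 0.28), Nox4 (2.90 ± 0.35), Ppbp (2.79 ± 0.52) and Rhpn2 (2.62 ± 0.21). The largest falls were those of the muscle genes Actc1 (-5.58 ± 1.49), Atp2a1 (-5.12 ± 1.24), Acta1 (-5.11 ± 1.24), Mylpf (-5.08 ± 1.29), Ckm (-4.84 ± 1.20) and Tnni2 (-4.74 ± 1.30). The mean of the muscle list was 9.87 and 9.36 in WT at P28 and 6.14 and 6.58 in WT at 4 months. It was 9.42 in Chop null replicate 2 at 4 months, so muscle in some nerves cannot be told apart from age in these falls. The P28 arrays stand apart in a labelling control. The spike-in transcript dap read 2.94 to 3.32 at P28 and 8.36 to 8.67 at the other ages. A difference through P28 in these comparisons cannot be told apart from one of array processing.

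From P5 to 4 months, compared after the data were seen because both ages carry the spike-in signal, 4557 genes changed (2634 higher, 1923 lower; 5330 unadjusted). Cyp2e1 (8.62 ± 0.14), Inmt (6.67 ± 0.24), Amy1 (6.03 ± 0.26), Aldh1a1 (5.86 ± 0.23), Tmem45b (5.67 ± 0.33) and Ces1d (5.49 ± 0.41) rose most. Nrk (-6.49 ± 0.16), Agtr2 (-6.00 ± 0.26), Dlk1 (-5.38 ± 0.17), Fbn2 (-5.33 ± 0.20), the neonatal myosin Myh8 (-4.83 ± 0.67) and Pclaf (-4.71 ± 0.23) fell most. All 29 cell cycle genes fell (median -2.99, adjusted p = 9.43e-29, and adjusted p = 0.0269 with an estimated correlation), and 14 of 17 antigen presentation genes rose (median 1.46, adjusted p = 4.26e-08, and adjusted p = 0.0269 with an estimated correlation). Cholesterol synthesis fell in 17 of 19 genes (median -1.28, adjusted p = 3.2e-10, and adjusted p = 0.239 with an estimated correlation). Ddit3 rose by 1.05 ± 0.19 and Asns by 1.81 ± 0.15 in these WT nerves. The Ddit3 values were 7.66 and 7.62 at P5 and 9.09 and 8.29 at 4 months. The higher one is from replicate 1, whose Gapdh 3' minus 5' signal was 2.12, so the size of the rise depends on that array.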

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

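Some tests were chosen only after the result was seen. They are those of direction at both ages, of second probe sets, of direction at P5 and of effect size at 4 months. Also chosen then were fits with a muscle or Gapdh covariate and those without Chop null P28 replicate 2, alone or with a WT 4-month array. The verdicts on second probe sets and on the muscle covariate at P28 and 4 months were made more cautious after their values were seen. That on degraded RNA at 4 months was opened, closed as further fits were seen, and then opened again.

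The tested difference of the S63del effect between ages singled out genes, given as log2 differences. From P5 to P28 the effect rose for Csrp2 (2.25), a LIM domain protein of smooth muscle, Aldh1a2 (1.96), Serpinb6b (1.85), Slc6a15 (1.85), Kcnk1 (1.74) and Ephb6 (1.73). It fell for Rpl27a (-3.29), Hspa1a (-2.40), Hspb1 (-2.37), Car6 (-2.32), Hba-a2 (-2.29) and Fbxo2 (-2.20). From P28 to 4 months it rose for Rpl27a (3.16), Hba-a2 (2.45), Agbl5 (2.22), Kdelr2 (1.87), Mgl2 (1.69) and Gatad1 (1.51). It fell for Cxcl14 (-2.44), Hspa1a (-2.39), Gria1 (-2.23), Kng1 (-1.75), Csrp2 (-1.56) and Nrk (-1.24). For Hspa1a the WT values rose, from 5.496 and 6.141 at P28 to 8.597 and 8.096 at 4 months. The S63del values stayed near level (8.564 and 8.691, then 8.897 and 8.63), so the smaller Hspa1a effect came from the rise in WT. From P5 to 4 months, a comparison added after the data were seen, the S63del effect rose for Chst2 (2.33), Chdh (1.86), Nsg2 (1.84), Vit (1.73), Serpinb6b (1.63) and Sema5a (1.57). It fell for Hspa1a (-4.80), Hspb1 (-3.53), Fbxo2 (-3.46), Hspa1b (-3.33), Asns (-2.50) and Tubb3 (-2.11). For Hspa1a S63del fell from 11.21 and 11.1 at P5 to the 4-month values above, while WT rose from 5.959 and 5.929. For Asns the WT values rose (6.73 and 6.76 at P5, 8.65 and 8.455 at 4 months) while S63del fell less (9.40 and 9.37, then 8.86 and 8.54).

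At P28, 473 genes were called in S63del against WT that were not called at P5. The 18S control parted the same arrays, as did, by narrow margins, the spread of values and Xist. For the 99 genes called at both ages an RNA or labelling difference at P28 is argued against, since 97% kept their direction. For the 473 it cannot be told apart from the genotype. Their second probe sets followed less often than those of P5 genes by 15.8 percentage points (81% of 226 against 96.7% of 123). But those of the 99 also followed in only 79.5% of 44 at P28. Of all 4956 genes with a second probe set, 66% followed at P28. Skeletal muscle in some nerves cannot be told apart either: with the muscle mean as a covariate 43.3% of the 473 remained called (205), and 66 of the 99. All 473 kept their direction, and their median change went from 0.679 to 0.665, a small shift beside the lost calls. The median of their SEs went from 0.155 to 0.169. An effect already present at P5 below the threshold may account for part, since 78% had the same direction at P5 (369 of 473, median 0.162 against 0.679 at P28), although both ages share 1 estimate of the spread.

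At 4 months no gene was called in S63del against WT by limma, with 577 at an unadjusted p under 0.05. In simulated data 24% to 32.67% of 1.5-fold rises were found in this comparison. Skeletal muscle cannot be told apart: 0 genes were called with the muscle mean as a covariate, which at P28 lowered the count from 572 to 274. The muscle mean also parted these arrays (6.14 and 6.58 in WT, 8.56 and 6.78 in S63del), so 0 calls decide nothing. Degraded RNA in WT replicate 1 cannot be told apart either. The planned test called 2 genes without replicate 1, which by its prediction goes against degraded RNA. But that fit leaves 1 WT array, and leaving out any array of the P5 comparison lowered the P5 count too. With Chop null P28 replicate 2 also left out, genes were called without either WT array, so those fits do not single out replicate 1. The Gapdh covariate gave 0, though both S63del arrays of that age also read high in the Gapdh 3' minus 5' signal (1.32 and 1.05). A smaller effect of the mutant protein at 4 months than at P5 may account for the pattern: the 298 genes called at P5 had a median shift of 0.71 at P5 in S63del/Chop null against Chop null, arrays not used to choose them, and 0.175 at 4 months in S63del against WT (24.6%, 241 above 0; 0.238 without WT replicate 1 and 0.124 without WT replicate 2). Within 1 comparison the median went from 0.833, inflated by the choice of genes, to 0.175 in S63del against WT and from 0.71 to 0.000858 (150 above 0) in S63del/Chop null against Chop null, and age of the animals stays open as untested.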

How the results depend on the processing

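Alternatives added after the data were seen are the fits without Chop null P28 replicate 2 (alone or with a WT 4-month array), without the P28 arrays, and with a muscle or Gapdh covariate, and the score with genes called at P5 only. Of 217 named gene results, 3341 of 3753 alternative values kept direction and side of the threshold, 411 lost the threshold and 1 reversed; 106 of the 217 lost it under at least 1 alternative, 23 of them with a change that also moved by over 1.5 times. It is Pdia4 in S63del against WT at P28, at -0.05225 with the mean of all its probe sets (adjusted p = 0.857, against 0.00122 to 0.118 under its other alternatives). The cause of the differences below was not tested unless stated. Zero handling was not run because the values are log2. Signal over background limits dim probe sets, whose removal under the 40th percentile (log2 6.19) took out 34 of the 217 named gene results and moved only 1 count by over 1.5 times, while others changed by less (P28 from 572 to 729 in S63del against WT). No list that the report calls in a direction changed sign when quantile normalized again, and no median of all genes moved by 0.1. The share of higher genes in S63del against WT at P28 went from 65.2% to 55.5%.

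Quantile normalized again, limma called 22 genes in Chop null against WT at P28, 2 in S63del/Chop null against S63del averaged over ages and 1 in the interaction at P5. With dim genes left out S63del/Chop null against S63del at P5 had 1. The 8 arrays of the age gave 901 (P5) and 59 (P28) in S63del against WT and 2 in the interaction at P5. They gave 586 (P5) and 84 (P28) in S63del/Chop null against Chop null, and 0 at 4 months in Chop null against WT and in S63del/Chop null against S63del, with 4 degrees of freedom for the spread. Array weights gave 1033 in S63del against WT at P5, 3 in Chop null against WT at P5, 6 (P5) and 3 (averaged) in S63del/Chop null against S63del, and 3 in the interaction at P5. They gave 134 for the S63del effect at P28 against P5 and 77 at 4 months against P5, and 935 (P5) and 14 (P28) in S63del/Chop null against Chop null. An intensity trend with robust estimation gave 1 in Chop null against WT at P5, 2 in S63del/Chop null against S63del averaged and 1 in the interaction at P5. The replicate block, though the numbers do not pair the samples, gave 10 for the effect at 4 months against P28. The list tests had 173 calls in the planned comparisons, 21 with an estimated correlation and 89 with fry. The score difference was 0.0729 (exact permutation p = 0.167) with genes called at P5 only and 0.212 (exact permutation p = 0.333) with genes called at both other ages. Neither exact permutation test could pass: the former scores 2 ages (8 arrays, smallest possible p = 0.0556) and the latter only 4 months (4 arrays, smallest possible p = 0.333), so they say nothing about stability.

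Without Chop null P28 replicate 2 and WT 4-month replicate 1, S63del against WT gave 572 (P5), 1761 (P28), 39 (4 months) and 1900 (averaged). Chop null against WT gave 1, 13 and 2 at the 3 ages and S63del/Chop null against S63del 2 (P28) and 3 (averaged). The interaction gave 2 (P5) and 1 (P28) and the S63del effect 213 (P28 against P5), 121 (4 months against P28) and 59 (4 months against P5). S63del/Chop null against Chop null gave 441 (P5) and 670 (P28). Without Chop null P28 replicate 2 and WT 4-month replicate 2 S63del against WT gave 31 at 4 months. Without the P28 arrays S63del against WT gave 564 (P5) and 455 (averaged), and S63del/Chop null against S63del averaged 2. The interaction at P5 gave 1, S63del/Chop null against Chop null at P5 399 and the effect at 4 months against P5 55. The muscle covariate gave 274 in S63del against WT at P28 and 7 for the effect at 4 months against P28. The Gapdh covariate gave 2 (P5) and 7 (P28) in Chop null against WT, 2 in S63del/Chop null against S63del averaged and 1 in the interaction at P5.

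Leaving out each array in turn, with the lone array assumed to vary like the other groups, S63del against WT ranged from 119 to 149 at P5 (119 without S63del replicate 2) and 113 (without WT replicate 1) to 663 at P28. It ranged from 0 to 12 at 4 months (12 without S63del replicate 1) and 499 (without S63del P5 replicate 2) to 948 averaged. Chop null against WT ranged from 0 to 1 at P5 (without Chop null replicate 1), 0 to 3484 at P28 and 1 to 824 averaged (both without Chop null P28 replicate 1) and 1 to 361 at 4 months (without WT replicate 2). S63del/Chop null against S63del ranged from 1 (without S63del replicate 1) to 4 (without S63del/Chop null replicate 1) at P5 and 1 to 1 at P28. It ranged from 1 to 17 at 4 months (without S63del/Chop null replicate 2) and 1 to 2 averaged (without S63del 4-month replicate 1). The interaction ranged from 0 to 1 at P5 (without Chop null replicate 1), 0 to 2239 at P28 (without Chop null replicate 1) and 0 to 17 at 4 months (without S63del/Chop null replicate 2). The S63del effect ranged from 17 (without S63del P28 replicate 1) to 45 for P28 against P5 and 5 (without S63del P28 replicate 1) to 19 for 4 months against P28. For 4 months against P5 it ranged from 13 (without WT P5 replicate 1) to 60 (without WT 4-month replicate 2). WT ranged from 5685 to 6660 (P28 against P5), 4859 to 6467 (4 months against P28) and 3551 to 4236 (4 months against P5). S63del/Chop null against Chop null ranged from 78 (without Chop null replicate 1) to 103 at P5, 538 (without S63del/Chop null replicate 2) to 5988 (without Chop null replicate 1) at P28 and 0 to 4 at 4 months (without Chop null replicate 2). The score difference ranged from 0.0134 to 0.0952 without S63del/Chop null 4-month replicate 1 or 2.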

Other observations

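The test of genes near Ddit3 and the test of precision were chosen before their results were seen, as were the other splits of the samples; the verdict on genes near Ddit3 was made more cautious after its value was seen.

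Genes outside the comparisons above moved with age in WT nerve. From P5 to 4 months, in limma, adipocyte genes rose in 13 of 14 cases (median 2.399, adjusted p = 0.239 with an estimated correlation) and axonal and neuronal genes in 9 of 15 with 1 fall (median 0.76, adjusted p = 0.0648 with an estimated correlation), while 10 of 18 tRNA synthetases fell. Myelin genes fell in 8 of 20 cases and rose in 1 (8 and 2 when adjusted over the list alone; median -0.19, adjusted p = 0.0182, and adjusted p = 0.539 with an estimated correlation): Gjc3 (-3.94 ± 0.31), Mag (-2.04 ± 0.23) and Dusp15 (-1.58 ± 0.22) fell and Ndrg1 rose by 1.07 ± 0.11. The mean of the myelin list was 11.72 and 11.73 in the WT arrays at P5, and 10.97 and 11.42 in WT replicates 1 and 2 at 4 months. The Gapdh 3' minus 5' signal was 2.12 in that replicate 1 and 0.08 in replicate 2, so RNA quality may account for part of the fall. The amino acid carrier Slc1a5 rose by 2.53 ± 0.15 and Slc7a5 by 1.70 ± 0.20.

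In the P5 nerves without Chop the mutant protein changed genes that mostly changed with Chop as well. In S63del/Chop null against Chop null the amino acid carrier Slc7a3 rose by 1.75 ± 0.17, Derl3 by 2.65 ± 0.24, Sdf2l1 by 2.20 ± 0.20, Gdnf by 1.86 ± 0.24, Btc by 1.46 ± 0.32 and Gadd45b by 1.05 ± 0.20. Scd1 (-1.37 ± 0.20), Idi1 (-1.37 ± 0.19) and Cd9 (-0.61 ± 0.09) fell. Of these genes Btc (adjusted p = 0.21) and Gadd45b (adjusted p = 0.0831) did not pass in S63del against WT at P5. Of 19 cholesterol genes 15 fell, with a median of -0.99 (adjusted p = 0.00412 with an estimated correlation).

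Few genes were called on loss of Chop. Too little precision to see 1.5-fold changes was put to a test: the 95% interval reached beyond 1.5-fold for 2.71% of genes in Chop null against WT and 1.79% in S63del/Chop null against S63del, averaged over ages, with a median width of 0.197 to each side. The prediction did not say which comparison counts, so the larger value was used, and it leaves open whether smaller changes may have been missed. These intervals are averaged over ages. At single ages, 1.5-fold rises simulated in Chop null against WT were found in 19.33% to 36% of cases at P5 and 26% to 32% at 4 months. At P28 the share was 34% to 50.67%. Most such changes would thus be missed at P5 and at 4 months. Genes carried along from the strain of the null allele would add calls, so their test decides nothing about few calls: 3% of the 100 measured genes nearest Ddit3 had an unadjusted p under 0.05 against 5.08% of the others, a ratio of 0.59.

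Other splits of the arrays within age were fitted in the same way, 100 of them. For S63del against WT averaged over ages 1 split, the real one, gave 854 genes. The highest other gave 609 and keeps the real labels at 2 ages. Among 100 splits this makes chance an unlikely source of the count but does not exclude it. Nor can the splits part the genotype from array differences that go with it, such as the 18S control at P28. For S63del/Chop null against S63del 2 splits, the real one included, gave as many as the real 1 gene, and the highest other gave 1. The gene is Ddit3, whose fall the null allele fixes, so the count decides nothing about chance, and nothing follows for other genes. For Chop null against WT 18 splits gave at least the real 1 gene and the highest gave 28, so chance cannot be excluded from this count alone. Here too the gene is Ddit3, whose fall the null allele fixes, so the count decides nothing about its fall. A split that keeps no age's real labels gave 20, and the cause of that count was not tested.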
